A study of Homo sapiens with 4 samples.

How the data were processed

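RNA of MHCC-97H cells, a human hepatocellular carcinoma line, was measured by paired-end RNA sequencing in 4 libraries, per the labels. The expression table holds TPM, a transcript abundance corrected for gene length, as deposited by the authors, with 1 row per gene and its Ensembl identifier, symbol, biotype and hg38 position. The submitters' processing notes name TopHat2 2.0.14, HTSeq, DESeq, edgeR and the hg38 build, and give no role for each tool. The kit named in the labels is a TruSeq RNA kit, and whether reads were counted by strand is not given in the sources used here. It is therefore unknown whether reads of overlapping genes on opposite strands were told apart in these values. TPM keeps no sequencing depth, so read totals are unknown and no counting interval is given.

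The table used here has 33478 rows, of which 18833 are protein-coding, 7633 are long intergenic noncoding and 5534 are antisense genes. Mitochondrially encoded genes and protein-coding genes of chromosomes 21 and 22 were not analysed here. The 4 columns sum to between 643063 and 850534 over the rows used here, and the sums differ between groups. TPM is defined to a fixed total per library, and the part of it outside these rows was 15.0% and 14.9% in control replicates 1 and 2, against 32.3% and 35.7% in UCK2 shRNA replicates 1 and 2. What makes up that part was not settled. Log2 differences of the values as deposited are therefore relative to it as well as to the genes used here.

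Libraries were grouped by their titles, with 2 control shRNA and 2 UCK2 shRNA libraries. The labels disagree in part: the description of control replicate 2 names another cell line number than its title, and that of UCK2 shRNA replicate 2 names UCK3 in place of UCK2. The extraction text of the labels speaks of retinas, so retina markers were read as levels. Genes with a mean TPM of at least 1 over the 4 libraries were kept, which left 14038. The groups were compared on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend). Tests were two-sided, with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. Each log2 difference is on the log2(TPM + 1) scale, which understates the change of genes at low levels. An exact permutation test of 2 against 2 cannot give a p below 0.333 and was not used. The count-based tests of the submitters' processing notes were not run, since TPM values are not counts.

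For 28 gene lists fixed before the data were examined, camera of limma compared members with all other genes at a preset correlation of 0.01. Lists with at least 5 genes kept were tested, which left 23, with Benjamini-Hochberg adjustment over them. camera with an estimated correlation and fry, which asks whether members move one way on balance, were run beside it. The estimated form of camera tests on the 2 residual degrees of freedom of the fit, which leaves it little power.

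Genes named in the text followed a rule fixed in advance. It takes UCK2, then the 12 genes in each direction with the largest change among those passing the threshold. These must average at least 5 TPM in the higher group, carry a symbol that is not a clone name and not overlap between groups. Where fewer than 10 pass, as here, the places are filled by the smallest unadjusted p. In each list the 2 members with the highest mean TPM are given where none passes. Genes named outside the rule are said to be so, and 1 gene that the rule takes is not reported here.

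Because the column sums differed, every result was also computed after median-ratio scaling of the genes kept, with factors of 1.19 and 1.00 for the controls and 0.918 and 0.928 for the UCK2 shRNA libraries. Other alternatives were other pseudocounts, other filters, quantile normalization, rescaling without the 50 most abundant genes, other variance models, the replicate number as a block, and leaving out each library in turn.

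The fit was tested on simulated values for the 14038 genes with the spread of these libraries and 200 changed genes. It called 0 of them at a 2-fold change, 182 at a 4-fold change and 197 at an 8-fold change. These counts were not split by gene level, so recovery of genes at low TPM is not shown. Unchanged genes called were 0, 9 and 9 in these runs, and 0, 11 and 4 in separate runs simulated from the values after scaling. The set test, run on 25 simulated sets of 30 genes, called the shifted set and 0 of the others. The simulated genes varied independently, so these runs do not test the preset correlation. In the data the estimated correlation ran from -0.03 for the STAT3 list to 0.56 for the cholesterol list. Figures were drawn with matplotlib 3.10.9.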

Results

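The data are gene expression profiles of MHCC-97H, a human hepatocellular carcinoma line chosen for its high metastatic capacity. Cells carried either a control short hairpin RNA (shRNA) or an shRNA against UCK2, with 2 libraries of each kind. UCK2 encodes uridine-cytidine kinase 2, an enzyme of pyrimidine salvage that phosphorylates uridine and cytidine. The design asks which transcripts differ when UCK2 is targeted. The titles of both UCK2 shRNA libraries carry the same letter, B, which the titles do not explain. If it names a single hairpin, its effects outside UCK2 cannot be told apart from those of targeting UCK2. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries. TPM values summed to 850379 in control replicate 1 and 850534 in control replicate 2, against 676811 and 643063 in the UCK2 shRNA libraries, so 15.0%, 14.9%, 32.3% and 35.7% of the fixed TPM total lay outside the genes used here. Between 22360 and 23952 genes were above 0 per library. No pair of libraries shared an identical value above 0, and correlations of log2(TPM + 1) across genes, which are not independent replicates, lay between 0.960 and 0.981. The highest was between control replicate 1 and UCK2 shRNA replicate 1, and the lowest between control replicate 2 and UCK2 shRNA replicate 2.

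UCK2, the targeted gene, was not separated by the labels. It lies on chromosome 1 from 165827531 to 165911618 on the plus strand of hg38 (ENSG00000143179), and its neighbour TMCO1 overlaps part of it on the opposite strand. UCK2 measured 135.7 and 93.6 TPM in control replicates 1 and 2, and 120.5 and 67.8 TPM in UCK2 shRNA replicates 1 and 2. The means were 115 ± 29.8 TPM in the controls and 94.2 ± 37.3 TPM in the libraries labelled UCK2 shRNA (SD, n = 2 each). The log2 difference of UCK2 was -0.31 ± 0.30 (SE; 95% interval -1.02 to 0.39; limma adjusted p = 0.640). After median-ratio scaling the UCK2 means were 103.8 ± 14.9 and 102.2 ± 41.1. The scaled log2 difference was -0.08 (95% interval -0.72 to 0.57, limma adjusted p = 0.990). A 2-fold fall lies outside this interval but inside the one as deposited, and both take part of their spread from other genes. The direction of the UCK2 difference turned with quantile normalization (0.0592) and without UCK2 shRNA replicate 2 (0.10). For this reason the groups are called libraries labelled control or UCK2 shRNA below, and each direction rests on the library titles alone, from which the descriptions of 2 libraries differ in the cell line number or the gene number.

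**Figure D1:**
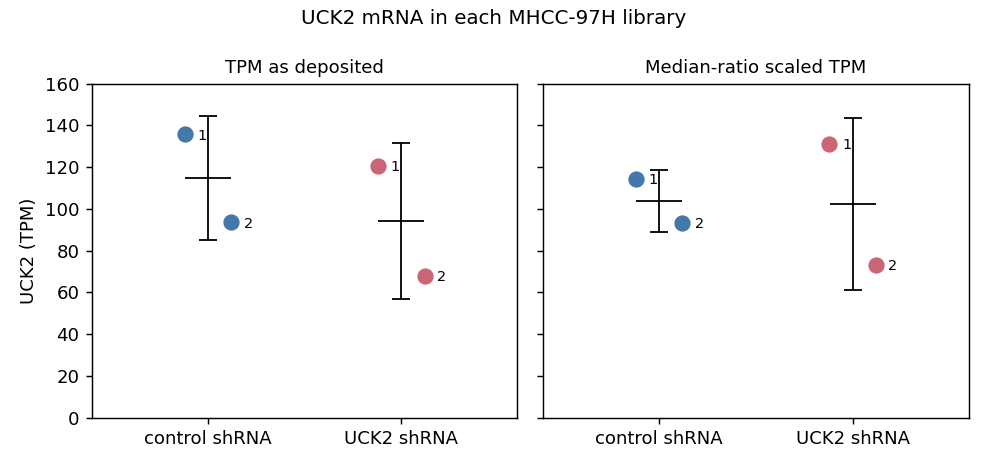
UCK2 in TPM (vertical axis) for each library, as deposited on the left and after median-ratio scaling on the right; points are libraries numbered by replicate, and bars are the mean and SD (n = 2). The groups overlap in both panels, with UCK2 shRNA replicate 1 at 120.5 TPM above control replicate 2 at 93.6 TPM.

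No gene passed the threshold in either direction. Of 14038 genes tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05, with a smallest adjusted p of 0.151. At an unadjusted p under 0.05, 194 genes were higher and 1962 lower in the libraries labelled UCK2 shRNA, where 702 are expected by chance. Most of the lower values followed a shift of the whole table. The median log2 difference of all genes tested was -0.22, and that of the 7562 genes averaging at least 10 TPM was -0.30. Median-ratio scaling brought the median to -0.01, and then 9 genes were higher and 0 lower at an adjusted p under 0.05, against 558 higher and 200 lower without adjustment. Scaled values are therefore given beside the deposited ones for every list tested and for some genes, and TPM values are as deposited unless said to be scaled. The scaled median of the genes averaging at least 10 TPM was -0.07, so scaled medians of lists of abundant genes are not to be read against 0. Groups did not overlap for 767 higher and 6235 lower genes, or 49.9% of genes, and for 31.5% after scaling, where chance gives 33.3%. In simulated data of this spread the test called 182 of 200 genes changed 4-fold and 0 of 200 changed 2-fold. Changes of 2-fold therefore lay below what these libraries resolve. Recovery was not split by gene level, so the 4-fold count does not show what is resolved for genes at low TPM.

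The genes with the smallest p among the higher ones were mainly noncoding, intronic or copied genes. None passes the threshold without scaling. EIF3CL, a near-identical copy of the translation initiation factor gene EIF3C (ENSG00000205609, chromosome 16, 28379579 to 28403879), measured 8.93 ± 3.38 TPM in the controls and 47.0 ± 6.45 TPM in the libraries labelled UCK2 shRNA (SD, n = 2 each). Its log2 difference was 2.31 ± 0.28 (SE, adjusted p = 0.180) and 2.54 after scaling (adjusted p = 0.0126). EIF3C itself, named outside the rule, measured 291 ± 6.25 and 208 ± 3.11 TPM, and reads that fit both copies make each value uncertain. SCARNA9, a small Cajal body RNA gene (chromosome 11, 93721513 to 93721865), measured 1.34 and 1.62 TPM against 14.3 and 29.0 TPM, a log2 difference of 3.12 ± 0.36 (adjusted p = 0.180; scaled 3.30, adjusted p = 0.0156). It lies within CEP295, its host on the same strand, which measured 3.62 ± 2.72 and 5.65 ± 1.47 TPM. PLCB1-IT1, a sense-intronic transcript of PLCB1 on chromosome 20, was listed at 0 in both controls and at 6.42 and 8.11 TPM in the libraries labelled UCK2 shRNA (scaled adjusted p = 0.0126). TMEM14E, within MBNL1 on chromosome 3, was listed at 0 in both controls and at 4.47 and 6.78 TPM (scaled adjusted p = 0.0345). The other 5 genes passing after scaling carry clone names.

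**Figure D2:**
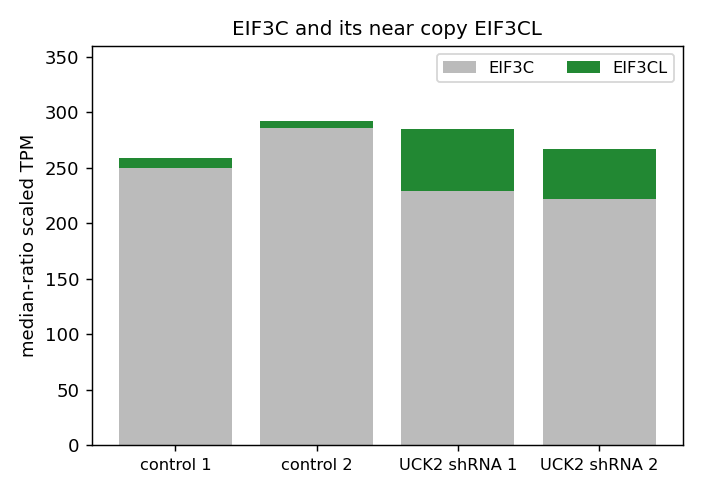
Median-ratio scaled TPM of EIF3C and EIF3CL (vertical axis) stacked for each library (horizontal axis). EIF3CL measures 9.54 and 6.52 in the controls and 56.1 and 45.7 in the libraries labelled UCK2 shRNA, while the sum lies between 259 and 293.

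The remaining genes of this group did not pass with or without scaling. MALAT1 (ENSG00000251562), an abundant nuclear noncoding RNA, measured 161 and 58.8 TPM in the controls and 411 and 1240.2 TPM in UCK2 shRNA replicates 1 and 2, a log2 difference of 2.86 ± 0.59 (SE, adjusted p = 0.294; scaled 3.10). A second row with the symbol MALAT1, named outside the rule, overlaps it on the opposite strand. That row averaged 2.42 TPM in the controls and 0 in the libraries labelled UCK2 shRNA (log2 difference -1.75, scaled -1.66). The antisense genes FARSA-AS1, within FARSA, and SNHG22, which overlaps MYO5B, had log2 differences of 2.15 and 1.51. The noncoding LINC00273 had 1.56. Among protein-coding genes, PRKCH, a protein kinase C isoform, measured 2.78 ± 0.136 and 7.96 ± 2.21 TPM. KIF18A, a mitotic kinesin, measured 2.39 ± 1.21 and 6.23 ± 0.766 TPM, and the transcription factor ZBTB20 measured 2.86 ± 1.84 and 7.79 ± 1.32 TPM. NOTCH2NL, a member of a family of near copies of NOTCH2, measured 24.3 ± 3.10 and 43.1 ± 9.78 TPM. The adjusted p of each gene that the rule takes in this paragraph was 0.294.

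The genes with the smallest p among the lower ones were abundant protein-coding genes, and none passed with or without scaling. BAX, a pro-apoptotic BCL2 family gene and p53 target on chromosome 19 (48954815 to 48961798), measured 384 ± 7.35 TPM in the controls and 215 ± 16.3 TPM in the libraries labelled UCK2 shRNA (SD, n = 2 each). Its log2 difference was -0.83 ± 0.15 (SE, adjusted p = 0.294) and -0.59 after scaling (adjusted p = 0.817). CSF1, the macrophage colony-stimulating factor, measured 92.5 ± 17.0 and 43.7 ± 1.54 TPM, with a log2 difference of -1.05 ± 0.19 (adjusted p = 0.294; scaled -0.82). JUND, a subunit of the AP-1 transcription factor, measured 107 ± 8.58 and 56.5 ± 4.22 TPM. MRPL10, of the mitochondrial ribosome, measured 56.9 ± 8.07 and 27.7 ± 0.805 TPM, and NDUFS6, of respiratory complex I, measured 139 ± 12.4 and 75.7 ± 7.73 TPM. DPM3, of dolichol-phosphate mannose synthase, measured 715 ± 103 and 391 ± 14.8 TPM. RPP21, a ribonuclease P subunit, measured 122 ± 0.291 and 69.1 ± 4.54 TPM. The log2 differences of SLX1A, PNKD, SLC2A4RG and C1orf122 were -0.94, -0.91, -0.84 and -0.95, and those after scaling -0.70, -0.67, -0.60 and -0.72. SLX1A shares near-identical sequence with SLX1B, so its level is uncertain. The adjusted p of each gene taken by the rule in this paragraph was 0.294.

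Of the 23 gene lists tested, 10 were lower than other genes in the libraries labelled UCK2 shRNA and 0 higher at the preset correlation of camera. Among genes with a mean TPM of at least 5, without scaling, 8 of these 10 were not called by camera. The cholesterol and ribosomal protein lists stayed called there (camera adjusted p = 0.0133 and 0.00213). With an estimated correlation 0 of 23 passed, and the adjusted p = 0.640 for each of the 10. That form of camera rests on the 2 residual degrees of freedom of the fit, so it had little power here. The estimated correlation lay below the preset one for the EGFR (-0.017) and autophagy (-0.013) lists. Correlation between genes therefore does not account for the loss of those calls. No member of any list passed over all genes. Adjusted over the list alone, 1 p53 target (BAX), 1 inflammatory mediator (CSF1), 1 ribosome biogenesis gene (BOP1, named after its value was seen) and 1 gene of the retina list (TUBB3) passed, all lower. After scaling 0 genes did so in any list. With scaling 2 lists were lower and 1 higher. With no filter on low values, lists are also compared with genes near 0 TPM, which have little room to fall. A list of expressed genes can then be called lower through the shift of the whole table alone. Calls with no filter, given below, therefore do not bear on the members of a list. Of the list members named below, 13 had a log2 difference below 0 as deposited and above 0 after scaling (0.02 to 0.23): SHMT2, FN1, CTSL, RHEB, B2M, HSP90B1, APOH, ALDH1A1, NPM1, RPL30, HSPA8, PECAM1 and CD68.

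Cholesterol and fatty acid synthesis was the list with the smallest scaled p. None of its 31 genes measured passed over all genes, 27 of 31 had a scaled log2 difference below 0, and the scaled median was -0.21. FDPS, farnesyl diphosphate synthase, measured 344 ± 2.53 TPM in the controls and 235 ± 51.2 TPM in the libraries labelled UCK2 shRNA. FDFT1, squalene synthase, measured 240 ± 1.51 and 154 ± 53.1 TPM (SD, n = 2). The list was lower with camera (adjusted p = 0.00122, and 0.00263 after scaling), though adjusted p = 0.640 with an estimated correlation, or 0.727 after scaling. The cell cycle and mitosis list had 37 of 47 genes below 0 after scaling and a median of -0.20. CKS1B, a cyclin-dependent kinase subunit, measured 674 ± 34.7 and 468 ± 118 TPM, and CDK4, a kinase of the passage into S phase, measured 415 ± 46.7 and 330 ± 32.9 TPM. The cell cycle list was lower with camera (adjusted p = 0.00664, and 0.0219 after scaling; adjusted p = 0.640 with an estimated correlation). With quantile normalization neither list was called (adjusted p = 0.0773 for cholesterol and 0.499 for the cell cycle), nor was the cell cycle list with a mean TPM of at least 5 (0.1001). The integrated stress response and unfolded protein response list was higher than other genes after scaling (adjusted p = 0.0411, against 0.0982 without scaling; adjusted p = 0.727 with an estimated correlation), with 8 of 30 genes below 0. Its most abundant members were the endoplasmic reticulum chaperones CALR, at 411 ± 19.4 and 277 ± 52.8 TPM, and HSP90B1, at 329 ± 155 and 290 ± 23.1 TPM, and their scaled log2 differences were -0.34 and 0.14. The stress response list was also called higher with quantile normalization (adjusted p = 0.000117), with a mean TPM of at least 5 (0.00216) and with rescaling without the 50 most abundant genes (0.0274).

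These 3 differences were carried by UCK2 shRNA replicate 2. The scaled median deviation of the cholesterol list from each gene's mean was -0.30 in that library, against 0.08 in UCK2 shRNA replicate 1 and 0.06 and 0.18 in the controls. For the cell cycle list it was -0.32 against 0.11, with 0.12 and 0.16 in the controls. For the stress response list it was 0.32 against -0.10, with -0.15 and -0.10 in the controls. Without UCK2 shRNA replicate 2 the adjusted p was 0.170 for the cholesterol list and 0.343 for the cell cycle list. Without UCK2 shRNA replicate 1 the stress response list was called higher without scaling (0.000573). Without UCK2 shRNA replicate 2 the direction of the stress response list turned to lower (adjusted p = 0.338), as it did with no filter on low values (0.902), and after scaling its adjusted p was 0.954. Without control replicate 1 the cell cycle list also missed the threshold (adjusted p = 0.0974), as did the stress response list after scaling (0.231).

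**Figure D3:**
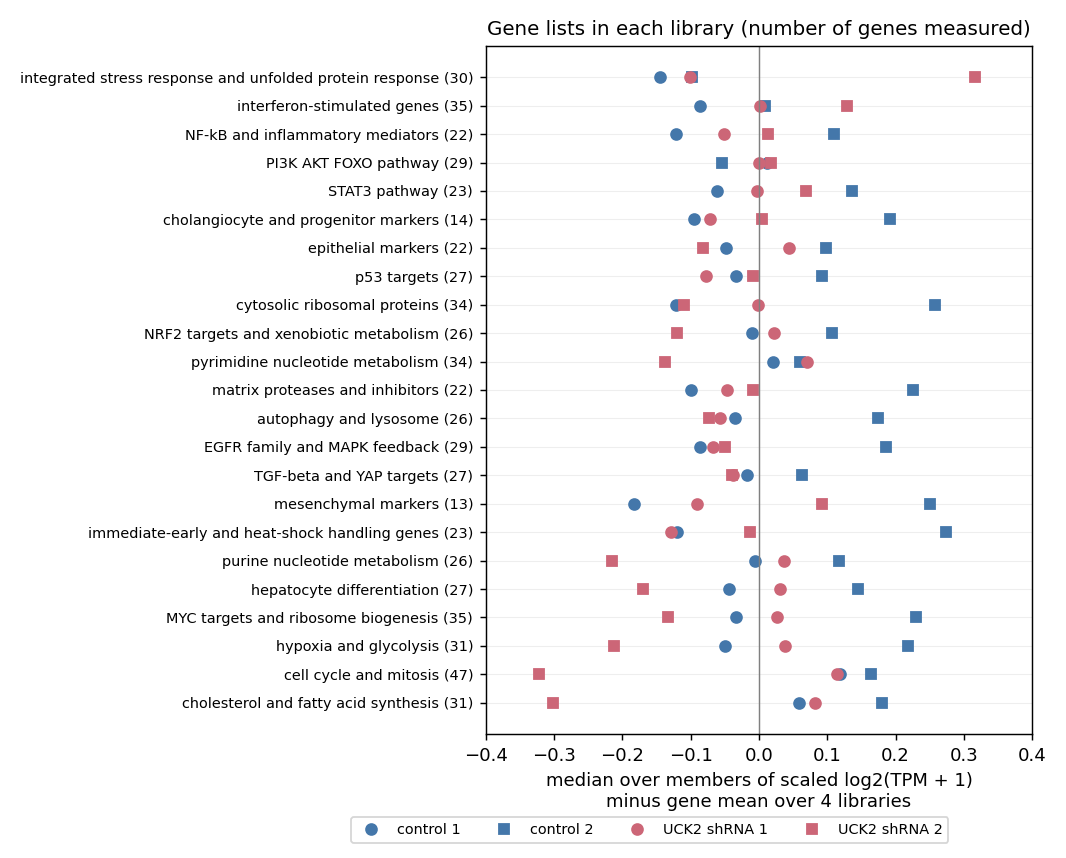
Median deviation of the members of each list from their mean over 4 libraries (horizontal axis, scaled log2(TPM + 1)), with 1 line per list and the number of genes measured in brackets; colours are groups, circles replicate 1 and squares replicate 2. UCK2 shRNA replicate 2 stands apart for cholesterol synthesis (-0.30) and the stress response (0.32), and control replicate 2 for cytosolic ribosomal proteins (0.26).

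The other 8 lists called without scaling were not called with it. The cytosolic ribosomal proteins were lower with camera (adjusted p = 3.24e-05; scaled 0.0727; adjusted p = 0.640 with an estimated correlation). RPL35 measured 5045 ± 626 TPM in the controls and 3121 ± 129 TPM in the libraries labelled UCK2 shRNA, and RPL30 measured 4000 ± 127 and 3508 ± 228 TPM (SD, n = 2). Control replicate 2 stood highest for this list, with a median deviation of 0.26 against -0.12 in control replicate 1, and without it the adjusted p was 0.737. MYC targets and ribosome biogenesis genes (adjusted p = 0.00664; scaled 0.0803) included the nucleolar genes NPM1, at 489 ± 158 and 473 ± 16.6 TPM, and FBL, at 485 ± 72.0 and 358 ± 74.2 TPM. Purine nucleotide metabolism (adjusted p = 0.00843; scaled 0.0653) included GUK1, guanylate kinase, at 286 ± 52.2 and 183 ± 27.1 TPM, and SHMT2, a serine hydroxymethyltransferase, at 229 ± 8.52 and 216 ± 25.5 TPM. Hypoxia and glycolysis (adjusted p = 0.00977; scaled 0.0653) included GAPDH, at 4665 ± 491 and 2820 ± 605 TPM, and PKM, pyruvate kinase, at 2527 ± 346 and 1700 ± 376 TPM. Each of these lists had an adjusted p = 0.640 with an estimated correlation. Without control replicate 2 the adjusted p was 0.0615 for the MYC and purine lists and 0.579 for the hypoxia list, and without UCK2 shRNA replicate 2 it was 0.108 for the purine and hypoxia lists.

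Autophagy and lysosome genes (adjusted p = 0.00489; scaled 0.0653) included SQSTM1, an autophagy receptor, at 1953 ± 177 and 1537 ± 23.7 TPM, and the lysosomal protease CTSD at 701 ± 58.5 and 472 ± 43.5 TPM. NRF2 targets and xenobiotic metabolism (adjusted p = 0.0179; scaled 0.306) included the aldo-keto reductases AKR1C1, at 2778 ± 179 and 2023 ± 266 TPM, and AKR1B10, at 2480 ± 16.1 and 1755 ± 392 TPM. The immediate-early and heat-shock genes (adjusted p = 0.0179; scaled 0.0653) included HSPB1, at 1010.3 ± 177 and 608 ± 87.6 TPM, and HSPA8, at 748 ± 26.1 and 657 ± 21.6 TPM. The EGFR family and MAPK feedback list (adjusted p = 0.0203; scaled 0.0653) included ERRFI1, a feedback inhibitor of EGFR, at 174 ± 43.0 and 143 ± 4.38 TPM, and MYC at 120.3 ± 1.68 and 88.5 ± 2.19 TPM. Each had an adjusted p = 0.640 with an estimated correlation. Without control replicate 2 the adjusted p was 0.229 for the autophagy list, 0.223 for the NRF2 list and 0.737 for the EGFR and immediate-early lists. Without UCK2 shRNA replicate 1 it was 0.106 for the EGFR list and 0.232 for the immediate-early list, and the NRF2 list gave 0.132 without control replicate 1 and 0.0744 without UCK2 shRNA replicate 2. By fry, which does not compare a list with other genes, 2 lists passed without scaling, EGFR family and autophagy (adjusted p = 0.05 each, just under the threshold), and 0 passed after scaling.

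Pyrimidine nucleotide metabolism, the pathway of UCK2, was not called. Its 34 genes measured had a scaled median of -0.08 (adjusted p = 0.108; scaled 0.254). It was called lower without UCK2 shRNA replicate 1 (adjusted p = 0.00687; scaled 0.0287) and with no filter on low values (0.000889), and gave 0.732 without UCK2 shRNA replicate 2 (scaled 0.815, with the direction turned). The call with no filter has the limit stated above for that setting. NME1, a nucleoside diphosphate kinase, measured 360 ± 52.6 and 245 ± 60.2 TPM, and the overlapping NME1-NME2 measured 1442 ± 179 and 1103 ± 168 TPM, so reads can be shared between them. The related kinase genes UCK1 and UCKL1, named outside the rule, measured 34.8 ± 1.29 and 24.9 ± 4.53 TPM, and 35.6 ± 1.86 and 29.7 ± 1.01 TPM. Their log2 differences were -0.48 and -0.25, and -0.24 and -0.02 after scaling.

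The lists of migration and cell identity were not called either. With no filter on low values camera called the epithelial list (adjusted p = 0.0260) and the matrix protease list (0.0155) lower, with the limit stated above. The mesenchymal list (13 genes, scaled median -0.12, adjusted p = 0.490, or 0.410 after scaling) included S100A4, at 10483 ± 1010 and 7564 ± 1297 TPM, and FN1, fibronectin, at 1888 ± 97.5 and 1643 ± 188 TPM. The epithelial list (22 genes, scaled median -0.04, adjusted p = 0.186, or 0.306 after scaling) included the keratins KRT8, at 2682 ± 611 and 1900.3 ± 153 TPM, and KRT18, at 796 ± 165 and 521 ± 85.2 TPM. Matrix proteases and inhibitors (22 genes, -0.09, adjusted p = 0.189, or 0.410 after scaling) were led by the cathepsins CTSL, at 796 ± 54.9 and 693 ± 91.7 TPM, and CTSD. Hepatocyte genes (27 genes, -0.14, adjusted p = 0.297, or 0.254 after scaling) included CEBPA, at 75.0 ± 12.3 and 48.8 ± 6.51 TPM, and APOH, at 61.9 ± 8.49 and 53.5 ± 9.84 TPM. Cholangiocyte and progenitor markers (14 genes, -0.03, adjusted p = 0.292, or 0.374 after scaling) included ALDH1A1, at 1526 ± 474 and 1356 ± 120 TPM, and SPP1, osteopontin, at 711 ± 54.8 and 597 ± 47.2 TPM.

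Signalling lists outside the calls gave the following values. With no filter camera called the p53 list (adjusted p = 0.00277) and the TGF-beta and YAP list (0.0109) lower, with the limit stated above. The p53 targets (27 genes, scaled median -0.05, adjusted p = 0.339, or 0.410 after scaling) included BAX and RPS27L, at 155 ± 29.4 and 161 ± 42.4 TPM. TGF-beta and YAP targets (27 genes, -0.12, adjusted p = 0.292, or 0.382 after scaling) included ID1, at 861 ± 53.5 and 629 ± 72.8 TPM, and ID3, at 434 ± 85.3 and 300 ± 19.7 TPM. The STAT3 pathway (23 genes, -0.02, adjusted p = 0.529, or 0.819 after scaling) included the survival genes MCL1, at 137 ± 14.1 and 105 ± 15.5 TPM, and BCL2L1, at 124 ± 12.2 and 92.2 ± 8.65 TPM. The PI3K, AKT and FOXO list (29 genes, 0.01, adjusted p = 0.529, or 0.410 after scaling) included RHEB, at 151 ± 9.84 and 136 ± 2.54 TPM, and AKT2, at 134 ± 12.1 and 109 ± 7.33 TPM. NF-kB and inflammatory mediators (22 genes, 0.04, adjusted p = 0.747, or 0.819 after scaling) included TNFAIP2, at 114 ± 3.28 and 95.6 ± 3.77 TPM, and CSF1. Interferon-stimulated genes (35 genes, 0.12, adjusted p = 0.339, or 0.374 after scaling) included B2M, at 1530 ± 88.2 and 1472 ± 79.0 TPM, and OAS1, at 224 ± 33.0 and 165 ± 16.4 TPM. For the last 3 lists and the stress response list the median without scaling lay below 0 while camera gave the higher direction, since it compares a list with all other genes.

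Markers of other cell types were read as levels, since few genes were kept. Among 13 fibroblast and stellate cell markers measured, LUM alone averaged at least 1 TPM, at 16.3 TPM. Of 12 endothelial markers 3 did, led by ESAM at 24.6 TPM, with PECAM1 at 22.5 ± 2.93 and 21.3 ± 0.775 TPM. Of 18 leukocyte markers 3 did, led by CD68 at 47.1 TPM, with CD79A at 7.62 ± 2.41 and 3.43 ± 0.815 TPM. Of 24 retina markers 3 did, led by the tubulin gene TUBB3 at 74.2 TPM, with ROM1 at 7.50 ± 1.02 and 5.50 ± 0.877 TPM, and the median marker of that list averaged 0.132 TPM. TUBB3 measured 95.9 ± 25.1 and 52.5 ± 0.925 TPM, with a log2 difference of -0.83 (adjusted p = 0.294; scaled -0.59). The list of mitochondrially encoded genes was not used here.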

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

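Each library left out in turn after scaling, and the crossed pairing, were chosen after seeing the data. The other alternatives were fixed before the data were examined. With other pseudocounts the counts of 0 genes higher and 0 lower and of 10 lists called were the same. The gene counts were also the same with eBayes without trend or with its robust form. camera does not use those settings, so the list count could not change there. At adjusted p under 0.1, or with a log2 difference of at least 1 in size, 0 genes passed. Median-ratio scaling called 9 genes higher and 3 lists, quantile normalization 8 genes higher and 1 list, and 8 of the 9 genes were shared. Rescaling without the 50 most abundant genes called 3 lists, no filter 16 lists, a mean TPM of at least 5 3 lists, an estimated correlation 0 and fry 2. With no filter, lists of other cell types also reached 5 genes, so its 16 calls are over more than 23 lists. The PI3K, NF-kB, interferon and stress response lists turned from higher to lower there, though none was called. The UCK2 difference turned to 0.0592 with quantile normalization and 0.0301 with the rescaling. With quantile normalization the direction turned for the ribosomal protein list (adjusted p = 0.499) and the NRF2 list (0.586), and the cholesterol and cell cycle lists were not called (0.0773 and 0.499). The cause was not tested.

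The replicate numbers were not shown to pair the libraries, since deviations of same-numbered libraries correlated at -0.21 across genes. The replicate block called 29 genes higher and 10 lower, and 9 lists. The NRF2 list was no longer called by camera with the block (adjusted p = 0.106). Among genes that the naming rule takes, the block called EIF3CL, SCARNA9, PLCB1-IT1, TMEM14E, MALAT1 and FARSA-AS1 higher and CSF1 lower. The crossed pairing called 91 genes higher and 636 lower.

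Leaving out a library assumes that the lone sample varies like the other group. Over these fits, with and without scaling, the UCK2 difference ranged from -0.72 to 0.34, genes higher from 0 to 242, genes lower from 0 to 108 and lists called from 1 to 10. Without control replicate 1 the counts were 242 higher and 108 lower, without control replicate 2 they were 32 and 21, and without either UCK2 shRNA library 0 and 0. The direction turned in some of these fits for the cell cycle list (adjusted p from 1.73e-07 to 0.815), the ribosomal protein list (0.000193 to 0.815), the EGFR list (0.00472 to 0.997) and the immediate-early list (0.00133 to 0.861), and for the stress response list (0.000179 to 0.954). Of the 9 genes called after scaling, 9 were called without either control and 0 without either UCK2 shRNA library, with the same sign each time. The cause was not tested. Among 74 other named genes, 13 had the other sign after scaling, and 0 called values took the other sign in any of the 19 settings. TPM keeps no depth, so its limit is unknown. The count-based test listed for count tables was not run, since the table holds TPM.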

Other observations

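The tests of biotypes, shares, library splits, matched lists and the sum of EIF3C and EIF3CL, and the reading of the 95% intervals, were chosen after the results were seen. The comparisons with and without median-ratio scaling that they start from were planned.

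Noncoding genes had a higher median difference than coding genes, though mainly through control replicate 2 and UCK2 shRNA replicate 2. After median-ratio scaling, the median log2 difference was 0.34 over 194 sense-intronic genes, which lie within introns of other genes, 0.15 over 997 long intergenic noncoding genes, 0.13 over 1175 antisense genes and -0.03 over 11624 protein-coding genes. Of the sense-intronic genes 76.8% were higher. Their median stayed above 0 without scaling (0.18) and with quantile normalization (0.17). The antisense median turned below 0 in both (-0.04 and -0.02), and the intergenic median without scaling (-0.02), each still above the protein-coding median (-0.25 and -0.03). The controls differed from each other by a median of 0.127 in the intergenic and 0.125 in the antisense genes, nearly as much as the groups. Long intergenic noncoding genes took 0.817% and 0.617% of the TPM of the genes kept in control replicates 1 and 2, against 0.813% and 1.11% in UCK2 shRNA replicates 1 and 2. MALAT1 carried much of the higher share, and without it the shares were 0.798% and 0.610% against 0.752% and 0.917%. Antisense genes took 1.15% and 0.870% against 1.15% and 1.16%.

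For the sense-intronic genes, 2 technical explanations were weighed. Their low level alone was argued against, since their median lay at percentile 100 of 10000 lists of protein-coding genes matched on mean TPM, whose median was 0.09. These lists came from the same 4 libraries and treat genes as independent, so the percentile does not measure the spread between libraries. A difference between libraries that does not follow the labels may account for much of it, because the 2 control libraries differed by 0.33 in these genes, about as much as the groups. Median deviations were 0.03 and -0.33 in the controls and 0.09 and 0.29 in the libraries labelled UCK2 shRNA. Whether a part of the difference goes with UCK2 shRNA stays open and was not tested.

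That UCK2 was not separated by the labels is the pattern that bears on every other value. Whether a scaling between libraries hides a UCK2 fall of 2-fold or more could not be decided. The lower end of the 95% interval was -0.72 after median-ratio scaling but -1.02 as deposited. Both ends take part of their spread from other genes. Each estimate fell short of a 2-fold fall, at -0.31 as deposited and -0.08 after median-ratio scaling. With quantile normalization it was 0.0592 and without the 50 most abundant genes 0.0301. An exchange of labels between control replicate 2 and UCK2 shRNA replicate 1 could not be decided: that split called 0 genes after scaling and 23 without, against 9 and 0 by the labels and 0 and 121 by the other split, and the 3 possible splits are too few for a share under 0.05. The TPM outside the genes used here followed the labels (15.0% and 14.9% against 32.3% and 35.7%). UCK2, whose levels led to the exchanged split, had a scaled log2 difference of -0.56 in that split (limma unadjusted p = 0.0385, adjusted p = 0.9999). The descriptions that differ from their titles are those of control replicate 2 and UCK2 shRNA replicate 2. They differ in the cell line number or the gene number and not in the group, so they name no such exchange. That the shRNA left UCK2 mRNA near its control level when cells were harvested may also be the case, and was not tested.

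The higher EIF3CL level, among the 9 genes called after scaling, may reflect how reads were assigned to EIF3CL and EIF3C. After scaling, EIF3CL was higher by 42.9 TPM and EIF3C lower by 42.5 TPM, so that their sum was 276 ± 23.8 in the controls and 276 ± 12.5 in the libraries labelled UCK2 shRNA, a log2 difference of 0.00409. EIF3CL took 3.68% and 2.23% of the sum in the controls and 19.7% and 17.1% in the libraries labelled UCK2 shRNA. Scaling as the source of the EIF3CL difference was argued against by its 95% interval without scaling, which began at 1.66. A change in the expression of the copy itself stays open and was not tested.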
